A study of Mus musculus with 23 samples.

How the data were processed

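The samples were anti-haemagglutinin immunoprecipitates of RiboTag spinal cord at 2 weeks of age, 23 libraries in 4 groups set by ChAT-Cre and the Gars genotype as the labels give them. Replicate numbers follow the order of the deposited samples and pair no libraries. The labels do not state that each library came from a separate animal, so p-values measure the spread between libraries. They also do not say what the leading number of a title is, and it was used only as a possible batch.

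The authors aligned reads with Bowtie2 2.2.0 and quantified genes with RSEM 1.2.12. Each deposited file gives, per gene, expected counts (expected_counts), transcripts-per-million (TPM) and fragments per kilobase and per-million reads (FPKM), beside gene length and effective length. The deposited expected counts are not normalised for depth. The deposited TPM was used for 1 alternative, without TMM scaling, and the deposited FPKM was not used here. The genome build and annotation are not given in the sources used here. Of 38924 gene IDs, 37607 matched GENCODE M21 on GRCm38 by identifier, and positions and gene types come from that match.

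Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM, quasi-likelihood tests). Only the groups compared entered a fit, except for the difference of the genotype effects and the average Cre effect, which used all 23 libraries. The Benjamini-Hochberg threshold was 0.05. Cre-enriched genes had an average Cre effect above 1 on the log2 scale with an adjusted p under 0.05. Fold changes are log2, mutant minus wild type or Cre minus no Cre. CPM values use TMM-scaled library sizes that include ribosomal RNA, over the 2 groups compared for Fgf21 in the genotype comparison and over all 23 libraries elsewhere.

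Of 538 symbols in 30 gene lists fixed before the data were examined (14 cell types and 16 pathways), 534 matched. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, then with an estimated correlation and with fry. List means (log2(CPM + 1)) and single values were compared with two-sided exact permutation tests. Some genes belong to more than 1 list, for example Sesn2.

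Genes were named by a rule also fixed before the data were examined: Chat, Gars and Rpl22 always, the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in the higher group, and up to 4 members of each list with the smallest p. Not every gene that the rule names is reported here. Predicted and unnamed models and sex-linked genes were left out of the rises and falls. Where fewer than 5 genes were called the 10 smallest p were used, without that exclusion, which names Gm6984. Atf4, Gm26924, Gm15662, Lars2 as a ribosomal RNA-like gene, and Xist fall outside it and were chosen after their values were seen.

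Total counts ranged from 9031654 to 19671869. The lowest chi-square per degree of freedom between replicates was 6.14 over 55 pairs, so variation between libraries exceeded counting error. In simulated data with known changes, edgeR called 27.5% of genes changed by 1 and 76.4% of those changed by 2 in the genotype comparison with Cre, and 8.6% and 59.3% in the Cre comparison of wild type. The latter held 93 genes changed by 1 and 86 by 2 among 11777, while 45.9% were called in the real data, so its shares may not carry over. Unchanged genes made up 8.8% of calls in the simulated Cre comparison of mutants and at most 3.3% in the others. A raised list was called and 0 other lists were. Genes were drawn independently there, so this does not show how camera behaves where genes vary together.

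Alternatives were RLE factors, library totals only, DESeq2 1.42.0, limma-voom with quality weights, robust estimation, no filter, a filter at 5 CPM, the title number as a block, a sex-linked covariate, all 23 libraries in one fit, a glial covariate, leaving out genes within 20 Mb of Gars, and leaving out each library. The block kept only libraries whose title number occurs in more than 1 of the groups fitted. In the genotype effect with Cre it left out numbers 18405 and 20304. In the genotype effect without Cre it kept only number 20301, so no block term was fitted there. Leaving out ribosomal RNA genes, title number 18405, or the 4 Cre libraries highest in glial markers was added after the data were seen. Chance was examined by refitting 100 splits of the libraries.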

Results

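RNA bound to tagged ribosomes was sequenced from the spinal cords of mice aged 2 weeks. The mice carried a haemagglutinin-tagged ribosomal protein, Rpl22, that Cre recombinase switches on, and ChAT-Cre directs it to cholinergic cells, among them motor neurons. Some mice also carried GarsC201R/+, a dominant allele of the glycyl-tRNA synthetase gene used as a model of inherited neuropathy. The 23 libraries fall into 4 groups: 5 Gars+/+ with ChAT-Cre (wild-type Cre), 6 GarsC201R/+ with ChAT-Cre (mutant Cre), and 6 of each genotype without Cre, where no tagged protein is made and the precipitate is background. Total expected counts per library ranged from 9031654 to 13636772 in wild-type Cre, from 11696397 to 14511394 in mutant Cre, from 12538407 to 18806506 in wild-type no-Cre and from 12042625 to 19671869 in mutant no-Cre libraries.

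A few genes took most of these counts. Gm26924, a gene model treated here as ribosomal RNA-like, held 64.7% ± 14.1 (SD, n = 5) of counts in wild-type Cre and 53.1% ± 9.65 (n = 6) in mutant Cre libraries, against 24.0% ± 6.62 (n = 6) and 23.8% ± 6.05 (n = 6) without Cre. Mitochondrial ribosomal RNA held 48.0% ± 8.83 and 54.7% ± 8.69 of counts in the wild-type and mutant no-Cre libraries (n = 6 each), and 4.89% ± 0.86 (n = 5) and 4.0% ± 2.12 (n = 6) with Cre. Without these and the related Lars2 and Gm15662 models, 1.21 to 4.47 M (mega) counts remained in wild-type Cre, 2.93 to 6.24 M in mutant Cre, and as few as 0.59 M in replicate 5 of the mutant no-Cre group.

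Comparing precipitates with and without Cre asks which transcripts the tagged ribosomes carried. Motor neuron transcripts rose. The choline acetyltransferase gene Chat (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989 in GENCODE M21 on GRCm38) stood at 56.1 ± 11.8 counts-per-million (CPM, SD, n = 5) in wild-type Cre and 33.7 ± 13.7 (n = 6) in mutant Cre libraries, against 2.25 ± 1.87 and 3.11 ± 2.64 without Cre (n = 6 each). Averaged over both genotypes, Chat rose by 4.20 on the log2 scale (SE 0.32, adjusted p = 5.78e-11). The 10 largest rises were those of Uts2b (6.14), Slc10a4 (5.62), Calcb (5.12), Lhx3 (5.05), Isl2 (5.04), Uts2 (5.02), Mnx1 (4.95), Sncg (4.91), Chodl (4.87) and Rprml (4.78), which include transcription factors and peptides of motor neurons. The 10 largest falls were those of Slc28a3 (-5.92), Fcrl6 (-5.90), Klk14 (-5.86), mt-Rnr1 (-5.74), Zfp457 (-5.61), Acer1 (-5.60), Hal (-5.57), Wdr38 (-5.45) and 2 gene models of the symbol Metazoa_SRP (-5.44 each). Gars rose by 1.81 (SE 0.22, adjusted p = 1.13e-07). Rpl22 fell by 0.45 (SE 0.18, adjusted p = 0.0349), a call lost without any 1 of 15 libraries and under 6 of the other alternatives, and it stood at 0.33 when libraries were scaled by their totals only.

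**Figure D1:**
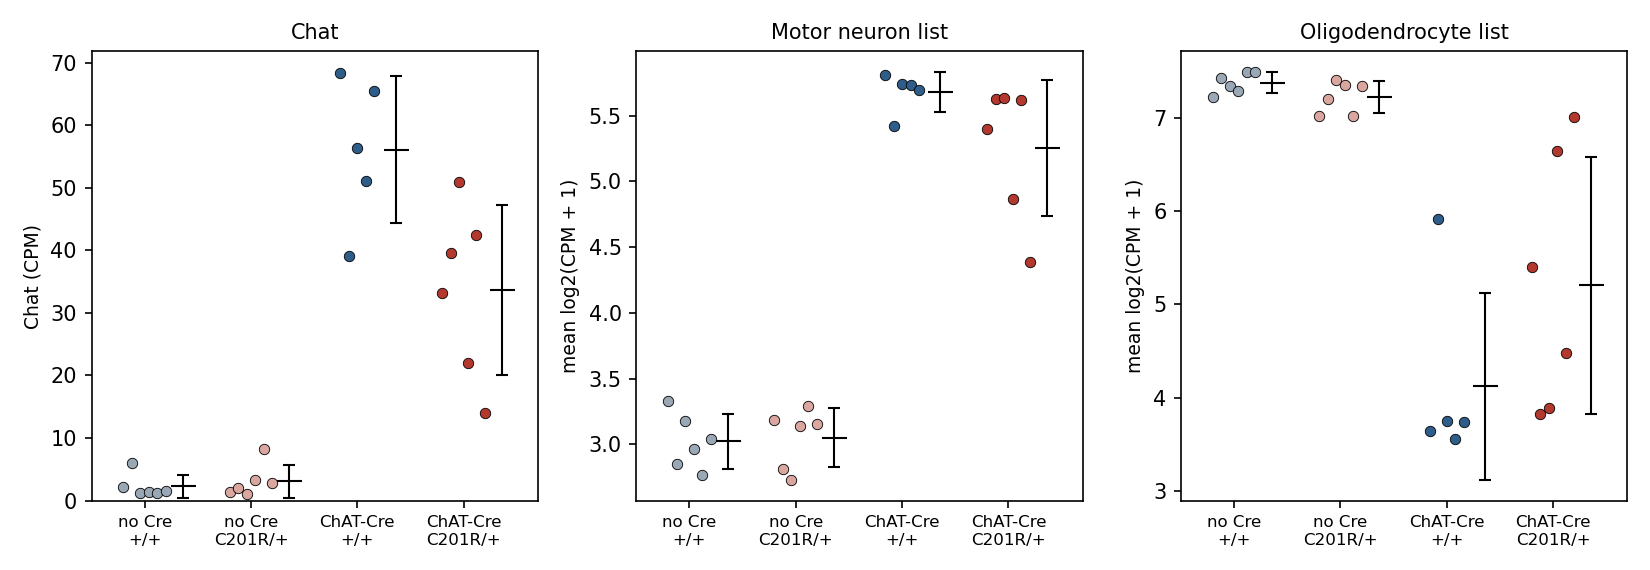
Chat (CPM), and the means of the motor neuron and oligodendrocyte lists (log2(CPM + 1)), for each of the 23 libraries by group, with the mean and SD beside the points. Chat ran from 39.1 to 68.4 CPM in wild-type Cre and from 13.9 to 50.8 CPM in mutant Cre libraries, and did not exceed 8.21 CPM without Cre.

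With edgeR, 5735 of 12485 genes differed between Cre and no-Cre precipitates in wild type, 2503 higher and 3232 lower with Cre. In mutants 4248 of 12741 differed, 1802 higher and 2446 lower, a split that reversed to 2355 higher and 1970 lower, 2525 and 2006, and 2677 and 2313 without replicates 1, 4 and 5 of mutant no-Cre, and to 2297 and 2287 without replicate 6 of mutant Cre. With scaling by library totals only, the count in wild type fell to 909, 407 higher and 502 lower, the split in mutants became 3266 higher and 275 lower, and the median of all genes moved by 0.07 in wild type and 1.24 in mutants on the log2 scale. In the average over both genotypes 8211 of 14468 genes differed, 3195 higher and 5016 lower.

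Cell type lists separated along the same axis. In the average over both genotypes, the motor neuron and cholinergic list had 17 of 19 tested members higher and 1 lower, over all genes and adjusted over the list alone, with a median of 3.50 (camera adjusted p = 2.81e-12, adjusted p = 0.0251 with an estimated correlation). Markers of other cells were lower: oligodendrocyte (14 of 14 members lower, median -2.25, camera adjusted p = 2.65e-07), oligodendrocyte precursor (9 of 9, -2.20, 3.05e-05), astrocyte (13 of 14, -2.13, 1.02e-05), erythroid (6 of 6, -2.05, 0.00839), microglia (11 of 14, -1.95, 0.0011), and endothelial and pericyte (9 of 13, -1.57, 0.0014). Adjusted over the list alone these counts were the same, except 12 of 13 for the endothelial and pericyte list. With an estimated correlation these 6 calls were lost, at adjusted p = 0.306, 0.264, 0.306, 0.408, 0.411 and 0.411. Exact permutation tests of the 6 list means passed in wild type (adjusted p = 0.0036 each). In mutants they passed for the oligodendrocyte (0.00648), oligodendrocyte precursor and astrocyte lists (0.00999 each). On the log2(TPM + 1) scale the exact p was 0.0649 for endothelial and pericyte in wild type, and 0.556, 0.496 and 0.632 for these 3 in mutants. That scale was not TMM-scaled, and in mutants it moved lists of other kinds upwards as well. In mutants alone 1 of 13 microglia (median -0.43), 0 of 13 endothelial and pericyte (-0.65) and 1 of 6 erythroid genes (-1.44) were called lower. Tests of the difference between the genotypes are given for each list with the last comparison. For the Cre effect in mutants, camera called the microglia, endothelial and pericyte, and erythroid lists lower (adjusted p = 0.0486, 0.0222 and 0.0222). These calls were lost with an estimated correlation (0.649, 0.635 and 0.572). The 3 list means did not pass exact permutation tests in mutants (adjusted p = 0.274, 0.198 and 0.0725). Inhibitory neuron (-0.92, camera adjusted p = 0.359), excitatory interneuron (-1.33, 0.492), meningeal fibroblast (-1.69, 0.0524), Schwann cell (-1.73, 0.173), ependymal (-1.54, 0.576) and skeletal muscle (-2.18, 0.0658) lists were not called in the average. Camera called the meningeal fibroblast (-2.69, adjusted p = 0.00158) and Schwann cell (-3.27, 0.00296) lists lower in wild type, and the skeletal muscle list (-1.95, 0.0222) lower in mutants, calls lost with an estimated correlation (0.245, 0.245 and 0.594). The sensory ganglion list had 2 tested members, too few for a test, with a median of -0.86.

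Several pathway lists differed with Cre, in both directions. All 12 tested heat shock genes were higher (median 1.69, camera adjusted p = 1.5e-07), as were 42 of 44 nuclear-encoded respiratory chain genes (1.27, 1.22e-15), 14 of 20 cytosolic tRNA synthetases (0.90, 7.54e-06) and 30 of 77 ribosomal protein genes, with 2 lower (0.43, 2.75e-05). The ribosomal protein list was called in wild type (median 0.87, camera adjusted p = 9.05e-08, adjusted p = 0.34 with an estimated correlation) but not in mutants (0.04, camera adjusted p = 0.337), and the difference itself was called by camera (-0.68, adjusted p = 6.03e-15) but not with an estimated correlation (adjusted p = 0.408). The axonal transport list, called in the average, was not called in mutants (0.18, camera adjusted p = 0.196), and the difference was not called (-0.16, camera adjusted p = 0.289). All 13 mitochondrially encoded respiratory chain genes were lower (-3.74, 7.11e-11). Axon injury (1.55, 0.00687), presynaptic (0.59, 0.00568) and axonal transport (0.51, 0.0302) lists were called higher. With an estimated correlation these 8 calls were lost, at adjusted p = 0.12, 0.12, 0.181, 0.481, 0.18, 0.181, 0.306 and 0.372. Adjusted over the list alone, the counts were 12, 42, 14, 28 higher with 2 lower, and 13 lower for the first 5 of them. Exact permutation tests of the heat shock, nuclear-encoded, cytosolic tRNA synthetase, mitochondrially encoded and axon injury list means passed in wild type (adjusted p = 0.0036 each) and mutants (0.00648 each). On the log2(TPM + 1) scale the exact p was 0.165 for cytosolic tRNA synthetases in wild type. The ribosomal protein mean passed in wild type (adjusted p = 0.0135, but exact p = 0.171 on that scale) and not in mutants (adjusted p = 0.392). Not called in the average were the integrated stress response (0.04, camera adjusted p = 0.0658), endoplasmic reticulum chaperone (0.13, 0.0658), mitochondrial tRNA synthetase (-0.15, 0.277), cholesterol biosynthesis (-0.31, 0.158), immediate early (0.09, 0.382), p53 target (-0.31, 0.492), interferon (-1.11, 0.435) and neuropilin and neurotrophin receptor (0.00, 0.567) lists. In mutants camera called the integrated stress response list higher (0.76, 14 members higher and 1 lower, adjusted p = 7.58e-05) and the cholesterol list lower (-0.43, 0.0275), calls lost with an estimated correlation (0.162 and 0.594). Camera called neither in wild type (-0.50, 0.632, and -0.30, 0.372), but the difference was not called for the cholesterol list (-0.03, 0.297), and the exact test of its list mean passed in wild type (adjusted p = 0.0036) and not in mutants (adjusted p = 0.0865). The stress response list mean differed by -0.171 in wild type (exact test, adjusted p = 0.0124) and by 0.797 in mutants (adjusted p = 0.00648). On the log2(TPM + 1) scale these were -0.0572 (exact p = 0.864) and 1.77 (exact p = 0.00216). That scale, without TMM scaling, moved other lists in mutants upwards too, so 1.77 is not particular to this list. The cytosolic tRNA synthetase mean differed by 2.14 there (0.915 in CPM) and the ribosomal protein mean by 1.68 (0.173 in CPM). The oligodendrocyte mean differed by -0.5 (-2.01 in CPM).

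Comparing mutant with wild-type Cre precipitates asks what the Gars mutation changes in the ribosome-bound RNA of cholinergic cells, the question the series title names. Genes of the integrated stress response, which ATF4 drives, rose in the mutants. Fgf21 (ENSMUSG00000030827, chromosome 7, 45613886 to 45615490) went from 0.0808 ± 0.114 CPM (SD, n = 5) to 16.4 ± 8.03 CPM (n = 6), with 3 counts over the wild-type group and 1713 over the mutants, a ratio of 230 (95% counting interval 78.5 to 1110; edgeR adjusted p = 5.68e-05). Gdf15 and Adm2 had 0 counts in the wild-type group, and against a floor of 3 counts over the group they were at least 27.1-fold higher (202 counts, adjusted p = 0.0118) and at least 21.6-fold higher (161 counts, adjusted p = 0.00988). Cass4 had 307 counts against 2, a ratio of 61.8 (17.0 to 512, adjusted p = 0.023). Such intervals and floors cover counting error only. The serine synthesis genes Psph (2.82, SE 0.30, adjusted p = 0.000805) and Psat1 (1.98, SE 0.25, adjusted p = 0.0027) rose, as did Nupr1 (5.30, SE 0.59, adjusted p = 0.00108), Fam129a (3.21, SE 0.40, adjusted p = 0.0027) and the cell-cycle inhibitor Cdkn1a (1.71, SE 0.22, adjusted p = 0.00277). The other large rises were those of Cdsn (4.68, adjusted p = 0.0193), Apobr (3.40, 0.0129) and Cox6a2 (3.19, 0.0253). Falls were smaller, among them those of Cd24a (-1.88, SE 0.28, adjusted p = 0.00988), Polr3g (-1.73), Ier3 (-1.66), Lgals1 (-1.59), Ano3 (-1.51), Mest (-1.28), Tbc1d4 (-1.16), Phyhip (-1.15) and Itpr3 (-1.03). Cd24a kept its call without any 1 library, while the other falls named here lost it without 3 (Ano3) to 10 (Tbc1d4) of the 11 libraries, as did Apobr without 1, Cass4 and Cdsn without 5 and Cox6a2 without 7. Gars itself was not called different (0.26, SE 0.22, adjusted p = 0.532), nor were Chat (-0.75, SE 0.28, adjusted p = 0.22) and Rpl22 (0.18, SE 0.20, adjusted p = 0.658).

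In all, edgeR called 41 of 12399 genes, 29 higher and 12 lower, with 2113 at an unadjusted p under 0.05. This count depended on the tool and on single libraries: DESeq2 called 413, 122 higher and 291 lower, limma-voom 862, 258 higher and 604 lower, and scaling by library totals only, which moved the median of all genes by 0.75, left 17, all higher. It was 1057 without replicate 2 of wild-type Cre, 423 higher and 634 lower, and 17, 10, 22 and 22 without its replicates 1, 3, 4 and 5, and 19 and 16 without replicates 3 and 5 of mutant Cre.

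**Figure D2:**
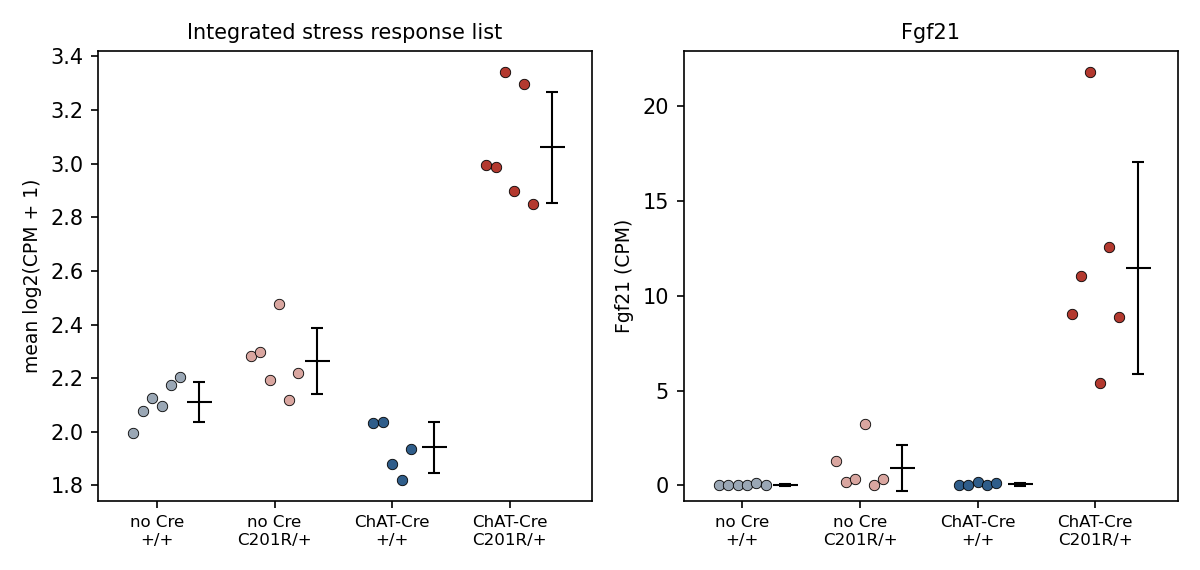
Mean of the integrated stress response list (log2(CPM + 1)) and Fgf21 (CPM, scaled over all 23 libraries) per library by group, with the mean and SD beside the points. The list mean ran from 2.85 to 3.34 in the 6 mutant Cre libraries and from 1.82 to 2.04 in the 5 wild-type Cre libraries.

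The integrated stress response list had the smallest camera p of the 29 lists tested, while 5 cell type lists had larger medians. Of its 35 tested members 15 were called higher and 0 lower by edgeR over all genes, and 30 were higher adjusted over the list alone. Leaving out 1 library gave 7 (without replicate 3 of wild-type Cre) to 23 called members (without replicate 2). The number was 25 with limma-voom and 7 with all 23 libraries in one fit. The median was 1.53, also with Gdf15 and Adm2 at their bounds (camera adjusted p = 5.86e-28, adjusted p = 0.00566 with an estimated correlation). The call with an estimated correlation was lost without replicate 2 of wild-type Cre (adjusted p = 0.0622) and under scaling by library totals only (adjusted p = 0.189). It was also lost without the 4 Cre libraries highest in glial markers (adjusted p = 0.0527). Atf4 was not called (0.86, adjusted p = 0.0678). The list mean was 3.06 ± 0.207 in mutant Cre (n = 6) and 1.94 ± 0.0955 in wild-type Cre libraries (n = 5; two-sided exact permutation p = 0.00216, adjusted p = 0.0324, or 0.0648 on the log2(TPM + 1) scale), and every mutant library lay above every wild-type library. Within the leading title numbers shared by both groups, 2 libraries against 2 each, the mutants were higher by 1.08 (20302) and 1.28 (20401), while number 18405 held mutants only and 20304 wild type only. The p53 target list was also called (median 0.60, 1 member higher, 3 adjusted over the list alone, camera adjusted p = 0.00317), with adjusted p = 0.194 with an estimated correlation. Its list mean was 3.17 ± 0.157 in mutant Cre (n = 6) and 2.63 ± 0.216 in wild-type Cre libraries (n = 5), without overlap. The exact permutation test gave adjusted p = 0.0324, or 0.13 on the log2(TPM + 1) scale. Within the shared title numbers its mean was higher in mutants by 0.38 (20302) and 0.801 (20401). Within 20302 the sex-linked gene Xist stood at 0.0314 to 0.0329 CPM in mutant and 14.9 to 18.2 CPM in wild-type Cre libraries. For both lists the difference within 20302 thus cannot be told apart from a sex-linked one. With the sex-linked covariate the integrated stress response median over all Cre libraries was 1.51.

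**Figure D3:**
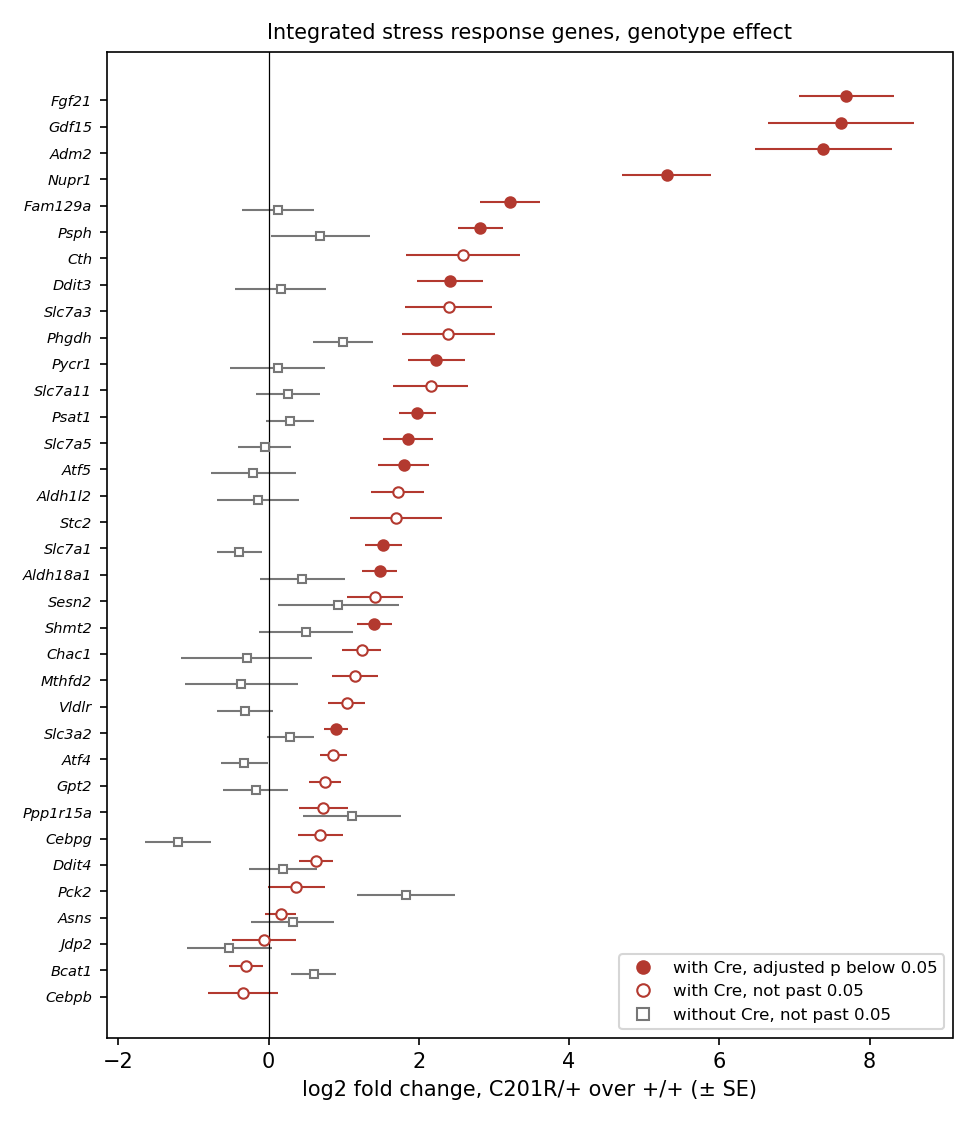
Log2 fold change of each integrated stress response gene between mutant and wild type, with its SE, in precipitates with Cre and without Cre. Of the 35 members tested with Cre, 32 were above 0, and of the 27 tested without Cre, 16 were.

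Cell type and housekeeping lists also differed by camera. The motor neuron list was lower (median -0.40, 0 of 19 called over all genes, 3 lower adjusted over the list alone, camera adjusted p = 0.000573), and oligodendrocyte (1.31, 0.00317), microglia (2.65, 6 of 6 adjusted over the list alone, 0.0206), and endothelial and pericyte (1.55, 0.00957) lists were higher. Ribosomal protein (-0.35, 3.68e-10), nuclear-encoded (-0.37, 5.12e-09) and mitochondrially encoded respiratory chain (-0.34, 0.00317) lists were lower. With an estimated correlation each of these 7 calls was lost, at adjusted p = 0.791. Of the 9 lists that camera called in this comparison, it still called 4 with the title-number block and 4 without title number 18405, in either direction. It still called 5 with the glial covariate and 3 without the 4 Cre libraries highest in glial markers. The medians of the motor neuron, ribosomal protein and both respiratory chain lists changed sign to 0.53, 0.52, 0.54 and 0.29 under scaling by library totals only, but stayed below the median of all genes, which that scaling moved from 0.06 to 0.79. Glial content differed within the Cre groups, and without the 2 mutant libraries of title number 18405 the oligodendrocyte median was 0.03 and the motor neuron median -0.18. That fit kept replicate 2 of wild-type Cre, whose oligodendrocyte list mean was 5.91, against 3.56 to 3.76 in the other wild-type Cre libraries. The oligodendrocyte list mean was 5.21 ± 1.38 in mutant (n = 6) and 4.12 ± 1.0 in wild-type Cre libraries (n = 5, exact permutation p = 0.173). The microglia list mean was 1.53 ± 1.27 in mutant (n = 6, 0.52 to 3.66) and 0.612 ± 0.162 in wild-type Cre libraries (n = 5, exact permutation p = 0.139). Microglia genes other than the 6 tested did not pass the count filter.

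No call was made for the other lists. Among those on translation and protein folding were cytosolic tRNA synthetases (median 0.16, camera adjusted p = 0.188), mitochondrial tRNA synthetases (-0.19, 0.606), endoplasmic reticulum chaperones (0.05, 0.662) and heat shock proteins (0.10, 0.727). Among neuronal lists were axon injury (0.01, 0.669), presynaptic (-0.17, 0.0938), axonal transport (-0.11, 0.0654), neuropilin and neurotrophin receptors (0.11, 0.606), inhibitory neuron (0.50, 0.072) and excitatory interneuron (0.14, 0.727). The remainder were astrocyte (0.99, 0.0938), oligodendrocyte precursor (1.29, 0.058), meningeal fibroblast (1.84, 0.301), Schwann cell (1.86, 0.606), ependymal (0.50, 0.637), erythroid (1.65, 0.281), skeletal muscle (1.45, 0.733), cholesterol biosynthesis (-0.11, 0.12), immediate early genes (0.14, 0.796) and interferon response (0.09, 0.988). The camera direction was the opposite of the median for the excitatory interneuron, axon injury, immediate early and interferon lists.

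Restricting the genotype comparison to Cre-enriched genes asks whether transcripts of the tagged cells themselves differed. Of 2106 such genes tested, edgeR called 101, 9 higher and 92 lower in mutants. The fold change was negative for 80.8% of the 2106, called or not, with a median of -0.30, while Cre-depleted genes had a median of 0.50. With the title number as a block, which leaves out numbers 18405 and 20304, 6 were called, 5 higher and 1 lower. Of the 434 enriched above 2 on the log2 scale, 7 were higher and 99 lower, with a median of -0.49. Under scaling by library totals only 5.75% of the 2106 were negative and their median was 0.57, below that of all genes (0.79) and of Cre-depleted genes (1.04), with 2 called, both higher. The count was 546 without replicate 2 of wild-type Cre, 9, 12, 12 and 6 without its replicates 1, 3, 4 and 5, and 10, 37, 11, 12 and 41 without replicates 1, 2, 4, 5 and 6 of mutant Cre. Without the 2 libraries of title number 18405, 10 were called, 6 higher and 4 lower.

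The same genotype comparison without Cre gives its background. Here edgeR called 0 of 12588 genes, with 565 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. Without the filter on low counts edgeR called 31. The smallest p-values were those of Zfp260 (-1.59, adjusted p = 0.951) and Cdkn1a (-1.42, adjusted p = 0.951), neither past the threshold. Gars (0.01, adjusted p = 0.996), Chat (0.37, 0.984) and Rpl22 (0.28, 0.971) were not called. The integrated stress response list had a median of 0.16 (27 members tested, camera adjusted p = 0.306). Its list mean was higher by 0.151 in mutants (exact permutation p = 0.0173, adjusted p = 0.292), but lower by 0.108 on the log2(TPM + 1) scale (exact p = 0.734). Fgf21, not tested by edgeR here, stood at 0.904 ± 1.22 CPM in mutant and 0.0184 ± 0.045 in wild-type no-Cre libraries (SD, n = 6 each, scaled over all 23 libraries, exact permutation p = 0.0152, adjusted p = 0.152), above 0 in 5 of 6 and 1 of 6 libraries. Camera called skeletal muscle (1.21, 0.000789), ribosomal protein (0.25, 9.89e-05), nuclear-encoded respiratory chain (0.29, 0.00716) and cytosolic tRNA synthetase (0.38, 0.0275) lists higher, and Schwann cell (-0.76, 0.00137) and meningeal fibroblast (-0.46, 0.0266) lists lower, and each of these 6 calls was lost at adjusted p = 0.63 with an estimated correlation. In simulated data of this design, 45.7% of genes changed by 2 on the log2 scale were called, and 2.2% of those changed by 1.

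The difference of the genotype effects asks whether the mutation acted differently with and without Cre. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) differed most firmly, by 3.10 (SE 0.44, adjusted p = 0.00146): it stood at 37.1 ± 10.7 CPM in mutant Cre (SD, n = 6) and 11.3 ± 2.86 in wild-type Cre libraries (n = 5), but at 6.14 ± 2.92 in mutant and 16.8 ± 5.98 in wild-type no-Cre libraries (n = 6 each). Clic4 differed by 1.90 (SE 0.35, adjusted p = 0.0437), with 44.0 ± 11.8 CPM in mutant Cre (n = 6) and 14.7 ± 5.73 in wild-type Cre libraries (n = 5), against 49.0 ± 12.5 in mutant and 61.9 ± 8.43 in wild-type no-Cre libraries (n = 6 each). The pseudogene Gm6984 had 0 counts in the 6 mutant Cre libraries and 140 counts in 4 of the 5 wild-type Cre libraries (adjusted p = 0.039), at least 117-fold lower against a floor of 3 counts over the group. Without Cre it ran the other way, with 48 counts in 5 of 6 mutant and 5 counts in 1 of 6 wild-type libraries. The integrated stress response list differed by a median of 1.47 (0 of 36 members called over all genes, 15 higher adjusted over the list alone, camera adjusted p = 5.06e-13, adjusted p = 0.000167 with an estimated correlation), while Fgf21 was not called for the difference (3.06, SE 1.75, adjusted p = 0.524).

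**Figure D4:**
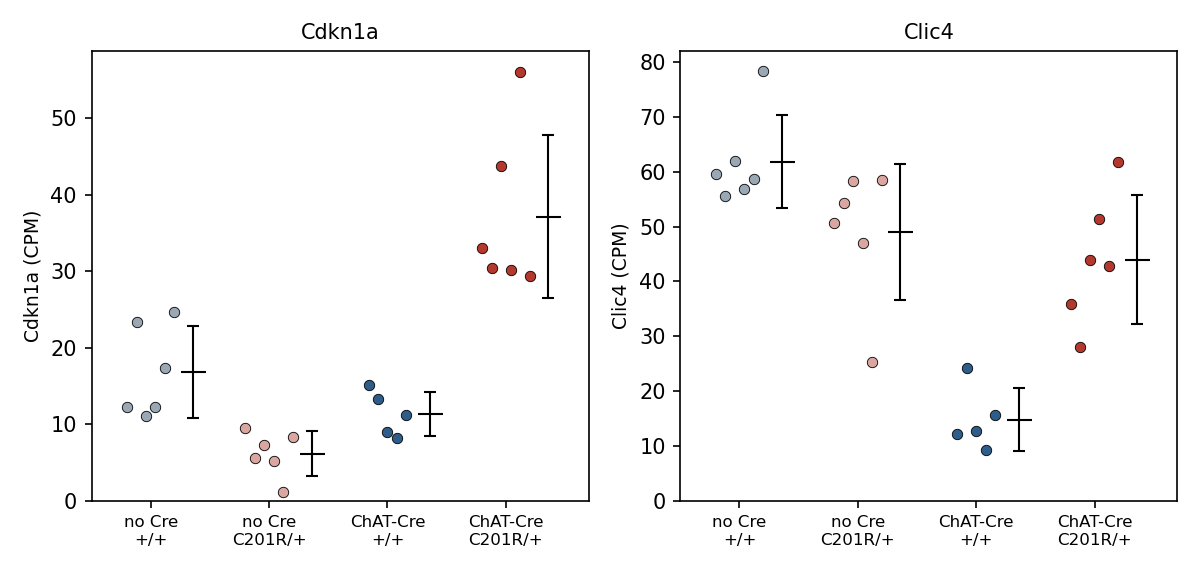
Cdkn1a and Clic4 (CPM) per library by group, with the mean and SD beside the points. Cdkn1a ran from 29.3 to 56 CPM in mutant Cre libraries, and its highest value in any other group was 24.6 CPM.

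These were the only 3 of 14468 genes called by edgeR for the difference, with 1524 at an unadjusted p under 0.05. The count was 8 without replicate 2 of wild-type Cre and 5 without replicate 4 of wild-type no-Cre. It was 1 without each of replicates 1, 4 and 5 of wild-type Cre, 3, 4 and 5 of mutant Cre, 1, 2, 5 and 6 of wild-type no-Cre, and 1, 4 and 5 of mutant no-Cre, and Cdkn1a was the gene that remained. Clic4 lost its call without 18 and Gm6984 without 13 of the 23 libraries, each left out alone. Cdkn1a lost its call under scaling by library totals only (adjusted p = 0.546), which moved the median of all genes by 1.07.

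Camera called 11 other lists for the difference, and with an estimated correlation it called none of them. Oligodendrocyte (1.44, camera adjusted p = 0.00016, adjusted p = 0.511 with an estimated correlation), oligodendrocyte precursor (1.25, 0.029, 0.553), microglia (3.13, 0.000183, 0.511), endothelial and pericyte (1.56, 0.00209, 0.532), meningeal fibroblast (2.56, 0.0135, 0.535), Schwann cell (2.87, 0.00584, 0.511) and p53 target lists (0.55, 0.0327, 0.242) were higher. Ribosomal protein (-0.68, 6.03e-15, 0.408), nuclear-encoded (-0.65, 6.12e-10, 0.408) and mitochondrially encoded respiratory chain (-0.19, 0.0452, 0.697) and motor neuron lists (-0.61, 0.00386, 0.511) were lower, but at 0.65, 0.71, 0.81 and 0.79 under scaling by library totals only, below the median of all genes, which that scaling put at 1.18. Over all genes 1 member of these lists was called, the p53 target Cdkn1a, and over the list alone 9 of 14 microglia, 4 of 13 endothelial and pericyte and 1 of 9 meningeal fibroblast genes were higher, as was Cdkn1a, and 1 of 19 motor neuron and 1 of 44 nuclear-encoded genes lower. Without title number 18405 the calls of the 6 lists of other cells and of the motor neuron list were lost, while that of the stress response list was not. Leaving out 1 library ended the call of the oligodendrocyte precursor list without replicate 2 of either no-Cre group, 4 of wild-type Cre, or 4 or 6 of mutant Cre, and that of the meningeal fibroblast list without replicate 4 or 6 of mutant Cre. It ended that of the p53 target list without replicate 2 of wild-type no-Cre, 2 or 6 of mutant no-Cre, 2 of wild-type Cre or 5 of mutant Cre, and that of the mitochondrially encoded list without any 1 of 13 libraries.

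The other lists were not called for the difference: erythroid (1.16, camera adjusted p = 0.361), inhibitory neuron (0.81, 0.102), excitatory interneuron (0.46, 0.982), astrocyte (1.00, 0.14), ependymal (1.15, 0.18), skeletal muscle (0.54, 0.254), cytosolic tRNA synthetase (0.05, 0.361), mitochondrial tRNA synthetase (-0.51, 0.0919), endoplasmic reticulum chaperone (-0.07, 0.352), cholesterol (-0.03, 0.297), axon injury (0.08, 0.595), immediate early (0.03, 0.985), heat shock (-0.21, 0.256), interferon (0.60, 0.341), neuropilin and neurotrophin receptor (0.27, 0.289), presynaptic (-0.02) and axonal transport (-0.16, 0.289). The sensory ganglion list had 2 tested members, too few for a test.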

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

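Of the tests in this part, the mixture test and the one leaving out 4 libraries were chosen only after the result was seen, and leaving out title number 18405 was an alternative added after the data were seen.

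Of 152 groups of values examined for a library far from the others, 17 held one, where chance gives about 1 in 20. Of these, 10 were in replicate 2 of wild-type Cre, whose values share the same cell types and are not independent. Its list means were 5.42 for motor neuron, against 5.7 to 5.81 in the other 4 libraries, 4.01 for astrocyte (2.34 to 2.6), 5.91 for oligodendrocyte (3.56 to 3.76), 2.96 for oligodendrocyte precursor (1.66 to 1.75), 0.896 for microglia (0.491 to 0.585), 2.33 for endothelial and pericyte (0.524 to 0.77), 2.41 for Schwann cell (1.41 to 1.69), 4.31 for erythroid (2.43 to 2.92), 4.45 for cholesterol biosynthesis (4.17 to 4.23), and 3.6 for the glial lists together (2.13 to 2.29). Elsewhere, the oligodendrocyte precursor mean was 4.13 in replicate 1 of wild-type no-Cre (4.46 to 4.64), and the neuropilin and neurotrophin receptor mean was 3.39 in replicate 3 of mutant Cre (3.61 to 3.66). Chat was 6 CPM in replicate 2 of wild-type no-Cre and 8.21 CPM in replicate 5 of mutant no-Cre. Rpl22 was 23.5 CPM in replicate 1 of wild-type no-Cre, Fgf21 0.11 CPM in replicate 5 of that group, where the other 5 were at 0, and the total 19.7 M (mega) counts in replicate 1 of mutant no-Cre.

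The genotype effect differed with and without Cre for Cdkn1a (3.10), Clic4 (1.90), the pseudogene Gm6984 (fitted value -12.91, no bound since a group is at 0) and the integrated stress response list (median 1.47). Camera called 11 other lists, among them markers of other cells, but none with an estimated correlation. For the count of 3 genes, 5 of 100 splits gave as many or more, the highest 191, many times the real count. These splits were drawn among the Cre libraries and, apart, among the no-Cre libraries. Chance is thus not excluded and the samples hold a structure of their own.

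Integrated stress response genes were higher in mutant Cre libraries. RNA of other cells in the 2 mutant libraries of title number 18405 is argued against as the whole cause, since the list median was 1.62 without them. The test of library scaling or ribosomal RNA reads decided nothing, since a scaling moves all genes of a library alike and leaves the gap between the list and all genes as it is (at least 1.46 under 3 scalings). A mixture with the RNA of the no-Cre precipitates cannot raise a gene above both sources, yet 26 of 35 members were above both. The Gars genotype may be the cause, a hypothesis found and tested on the same data, while title numbers overlap the groups only in part and other differences between the mice were not tested.

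The motor neuron list was lower and glial lists higher in mutant Cre libraries. Without title number 18405 the oligodendrocyte median was 0.03. This decides little, since replicate 2 of wild-type Cre, with an oligodendrocyte list mean of 5.91, was kept. The other wild-type Cre libraries lay at 3.56 to 3.76, below the lowest mutant Cre library (3.83). RNA of other cells in the 2 libraries of number 18405 thus remains only a candidate explanation of the glial part. The Gars genotype cannot be told apart from that RNA. Within title number 20401 the oligodendrocyte mean was lower in mutants (-0.591) and within 20302 higher (0.866), both from 2 libraries against 2. The first is within their spread and rests on replicate 2: wild type lay at 3.64 and 5.91, mutants at 3.9 and 4.48. Within 20302 the mutants were low and the wild type high in the sex-linked gene Xist, so the second cannot be told apart from a sex-linked difference.

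Cre-enriched genes were lower in mutant Cre libraries. Leaving out the 2 libraries of title number 18405, with the outcome predicted before it was seen, left 4 called lower where all libraries gave 92, but this decides nothing, since leaving out replicate 5 of wild-type Cre alone also left 4, and replicate 1 of either Cre group 7. A second test, chosen after the first value was seen, left out the 4 Cre libraries highest in glial markers, these 2 and replicate 2 of wild-type Cre among them, and 259 were called lower, which decides nothing either, since leaving out that replicate alone gave 528. As the counts turn on single libraries, RNA of other cells, in the 2 or the 4 libraries, cannot be told apart from the Gars genotype. The median over the enriched genes was -0.30 with all libraries, -0.21 without the 2, -0.27 without the 4, -0.17 with the planned glial covariate (10 called lower), and 0.57 under scaling by library totals only, below that of all genes there (0.79) as with all libraries (0.06).

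Other splits of the same libraries showed how often chance gives as many calls, with 100 splits each. For the Cre effect in wild type only the real split reached 5735 genes (1 of 100, highest other 2843), and in mutants only the real split reached 4248 (1 of 100, highest other 1183). This excludes chance for both only for splits that ignore title numbers. Among the mutants only number 18405 held both Cre and no-Cre libraries. For the 101 Cre-enriched genes only the real split reached the count (1 of 100, highest other 5). The enriched genes were chosen from a fit with the real groups and kept for every split, which may favour the real split. Chance is thus argued against only for this fixed choice of genes and for splits that ignore title numbers. Number 18405 holds mutants only, and the count was 10 without it and 6 with the title-number block. The block leaves out 18405 and 20304 too, so the 2 counts overlap and do not show what blocking alone does. For the 41 genes of the genotype effect with Cre, 5 of 100 splits gave as many, so chance is not excluded for that count. The others called up to 508 genes, several times the real count, which points to a structure of the samples: all 4 placed replicates 1, 3 and 4 of wild-type Cre together with mutant libraries and replicate 2 on the other side. Without Cre all 100 splits gave at least the real 0 genes, the highest 22.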

How the results depend on the processing

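In this part, leaving out ribosomal RNA genes, title number 18405 or the 4 Cre libraries highest in glial markers was chosen after the data were seen. No paired analysis was possible because replicate numbers only follow the order of the samples and pair no libraries. Leaving out libraries with totals far under their group's median removed 0 libraries, so it gave no value. Those totals include ribosomal RNA, so the rule could not pick out replicate 5 of mutant no-Cre, with 0.59 M counts without ribosomal RNA-like genes. Unless said otherwise, the cause was not tested.

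The integrated stress response list kept its direction and its camera call under every alternative run, with a median of 1.48 to 2.27, and of 1.41 to 1.66 when each library was left out. Fgf21, Nupr1, Fam129a, Psph, Psat1 and Cdkn1a kept their call in the genotype effect with Cre under all 26 alternatives. Gdf15 and Adm2 lost theirs with all 23 libraries in one fit (adjusted p = 0.42 and 0.0541), Adm2 also with the title-number block (0.0756), and DESeq2 gave neither an adjusted p. With an estimated correlation the list call was lost under library totals only (adjusted p = 0.189), without the 4 libraries (0.0527) and without replicate 2 of wild-type Cre (0.0622), over a range down to 6.96e-08. On the log2(TPM + 1) scale its list mean differed by 1.72 and the adjusted exact p became 0.0648.

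Counts depended on the processing. The Cre effect in wild type (5735) became 909 with library totals only and 3701 with a filter at 5 CPM, which tests fewer genes. In mutants (4248) it became 6990 with limma-voom and 8175 with no filter. The genotype effect with Cre (41) became 17 with library totals only, 413 with DESeq2, 862 with limma-voom, 89 with no filter, 19 with the title-number block, 63 with the sex-linked covariate, 11 with all 23 libraries in one fit and 540 without the 4 libraries. Of the 41 genes, DESeq2 called 39 and limma-voom 41. Without Cre (0) no filter gave 31. The difference of the genotype effects (3) became 1 with library totals only, 42 with DESeq2, 169 with limma-voom and 9 with no filter. Among Cre-enriched genes (101) the count became 2 with library totals only, 301 with DESeq2, 529 with limma-voom, 162 with no filter, 6 with the block (5 higher, 1 lower), 161 with the sex-linked covariate, 3 with all 23 libraries, 19 with the glial covariate, 10 without title number 18405 and 286 without the 4 libraries. The number of lists called (9) became 1 with an estimated correlation, 2 with fry, 14 with the sex-linked covariate and 4 without the 4 libraries. The Cre-enriched gene set held 2125 genes, and 447 above 2.

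Leaving out 1 library at a time gave 10 (without replicate 3 of wild-type Cre) to 1057 genes (without replicate 2) for the genotype effect with Cre, 6 (without replicate 5 of wild-type Cre) to 546 (without replicate 2) among enriched genes, 1 to 8 (without replicate 2 of wild-type Cre) for the difference, and 7 to 14 lists (without replicates 2 and 5 of mutant Cre). The Cre effect stayed at 4878 to 6474 genes in wild type and 3451 to 4990 in mutants.

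With library totals only, genotype effects with Cre changed sign, with a shift of all genes of 0.75, among them Calca 0.21, Cck 0.24, Chat 0.22, Chodl 0.19, Cox5b 0.34, Dctn1 0.19, Dusp1 0.02, Dync1i1 0.21, Fdft1 0.34, Hspb1 0.40, Ifi27 0.12, Kif5a 0.44, Mvk 0.14, Ndufb10 0.21, Ndufb7 0.19, Nefm 0.00, Rpl35 0.15, Rpl35a 0.04, Rps20 0.02, Sv2c 0.38, Syvn1 0.47, Unc13a 0.42 and mt-Nd4l 0.29, and the medians of the ribosomal protein (0.52), mitochondrially encoded (0.29), motor neuron (0.53) and nuclear-encoded respiratory chain (0.54) lists. For the difference these lists gave 0.65, 0.81, 0.79 and 0.71, Chat 0.28, Nkiras1 0.00 and Rpl22 0.93. Without Cre, Chat gave -0.06, Gars -0.26 and Rpl22 -0.02, and Rpl22 gave 0.33 in the average Cre effect. On the log2(TPM + 1) scale the list means of axonal transport (0.75), cholesterol (0.774), ribosomal proteins (0.693), mitochondrial tRNA synthetases (0.383), mitochondrially encoded (0.523), motor neuron (0.435), nuclear-encoded (0.689) and presynaptic (0.775) lists changed sign. Every list mean was higher in mutants on that scale, which was not TMM-scaled, the smallest difference being 0.383.

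Some marker genes of other cells, and a few other results, changed sign under alternatives on libraries or covariates. Under the glial covariate, Cldn11 gave -0.35, Col3a1 -0.72, Gfap -0.35, Hba-a1 -0.05, Mag -0.56 and the endothelial list -0.10. With the title-number block, Cldn11 gave -0.13, Col3a1 -0.77, Gfap -0.36, Gpr17 -0.04, Mag -0.43 and the mitochondrially encoded list 0.03. Without the 4 libraries, Cldn11 gave -0.16, Col3a1 -1.07, Csf1r -0.08, Gfap -0.20, Hba-a1 -0.29, Mag -0.58, Rpl22 -0.06 and the mitochondrially encoded list 0.18. Without title number 18405, Cldn11 gave -0.16, Col3a1 -0.59, Gfap -0.28, Mag -0.29, Rpl22 -0.07 and the mitochondrially encoded list 0.02, and 0.28 for the difference. With limma-voom, Rpl22 gave -0.09 with Cre and Gars -0.03 for the difference. Effects near 0 also changed sign. Without Cre, the block kept only the libraries of number 20301, with no block term, and gave Chat -0.83 and Gars -0.53. No filter gave Gars -0.03 there. The block gave Rpl22 0.02 for the difference. Without Cre, leaving out each library gave Chat -0.12 (without replicate 5 of mutant no-Cre) to 0.94, and Gars up to 0.36. Gars gave -0.03, -0.13 and -0.03 without replicates 1, 4 and 6 of mutant no-Cre and -0.16, -0.08 and -0.07 without replicates 1, 4 and 5 of wild-type no-Cre. For the difference, Gars gave -0.09 (without replicate 2 of wild-type no-Cre) to 0.41, and the mitochondrially encoded list, -0.41 at its lowest, gave 0.02 without replicate 2 of wild-type Cre and 0.01 without replicate 5 of mutant no-Cre.

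After ribosomal RNA as few as 0.59 M (mega) counts remained in a library. In simulated data 2.2% of genes changed by 1 were called without Cre, where the common coefficient of variation was 0.60, and 27.5% with Cre, where it was 0.39. Depth and variation between libraries were not tested apart.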

Other observations

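The test on noncoding RNA in this part was chosen only after the result was seen.

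Long intergenic noncoding RNAs were depleted from Cre precipitates: 193 of 257 were called lower, against 4294 of 13312 protein-coding genes (odds ratio 6.33, 95% interval 4.74 to 8.56, Fisher exact p = 5.15e-44). Antisense RNAs were called lower in 164 of 237. Genes are not independent replicates. RNA outside tagged ribosomes may make up much of the no-Cre background, a hypothesis that this result is in line with.

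A strain difference linked to Gars could place called genes near it. Of 148 tested genes within 20 Mb of Gars, 21 had an unadjusted p under 0.05 in the genotype effect with Cre, against 2092 of 12251 others (odds ratio 0.803, 95% interval 0.479 to 1.28, Fisher exact p = 0.441), and 0 were called by edgeR, so an excess of more than this interval allows is argued against.

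Xist was above 5 CPM in 3 libraries of each of the 4 groups. It reached at least 334 CPM in those of wild-type no-Cre, 194 in mutant no-Cre, 14.9 in wild-type Cre and 11.7 in mutant Cre. In 1 wild-type no-Cre library both Xist above 5 CPM and at least 5 counts of 4 Y-linked genes were found. Within title number 20302 the mutant Cre libraries were low and the wild-type Cre libraries high in Xist. Genotype and sex-linked differences thus cannot be told apart within that number.

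Residuals of libraries in different groups had a mean correlation across genes of -0.007 (34 pairs) when they shared a title number. For different numbers it was 0.004 (164 pairs). Pairs within a group were left out of these means. Within groups the chi-square per degree of freedom went both ways. It was 13.09 for replicates 4 and 6 of mutant Cre, which share a number. Between either and the other mutant Cre libraries it was at least 37.56. In wild-type Cre it was 10.25 for replicates 3 and 5, which share a number, and 6.14 for replicates 3 and 4, which do not.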
